A study of Mus musculus with 4 samples.

How the data were processed

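Brown preadipocytes, the committed precursors of brown fat cells, were sorted from mice of 8 weeks as lineage-negative cells carrying CD29, CD34 and Sca1. The control sample came from mice with floxed EP3 alleles, and the EP3 conditional knockout (cKO) sample from mice that also carried Cre under Myf5. EP3, encoded by Ptger3, is a receptor for prostaglandin E2. Each genotype was represented by 1 sample pooled from approximately 30 mice. Per the labels' protocols, total RNA was immunoprecipitated with an antibody against N6-methyladenosine (m6A), a methyl mark on adenosine. The bound RNA (IP) was labelled with Cy5 and the RNA left in the supernatant (Sup) with Cy3. The 4 samples therefore lay on 2 arrays, 1 per genotype, with the same dye orientation on both.

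Per the file headers, the arrays were read with Agilent Feature Extraction 11.0.1.1, which the submitters' processing notes also name. The deposited scanner files give the processed signal as an intensity on a linear scale, with the local background subtracted and both dyes normalised within the array by a linear and a Lowess step. Pixel medians of spot and background are in the deposited files as raw intensity. The deposited files also give flags of 0 or 1 for outliers, saturation and signal well above background. The authors' deposited value table holds log2 values of 48973 probes. Set against the scanner values, each of its columns equalled log2 of that channel's processed signal, averaged over a probe's spots, minus 1 constant. The constants were 11.92 for control IP, 12.23 for cKO IP, 11.51 for control Sup and 11.36 for cKO Sup. What they were taken from is not given in the sources used here. The table's column medians were -3.36, -3.85, -2.97 and -3.00 in the same order. Its sample columns without a mapped sample numbered 0.

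Each array held 62976 spots, of which 61141 were array probes, 1439 had a control type and 396 were treated as controls because of their names. A probe was used when its spots carried no outlier flag and were well above background in both channels of both arrays, for at least 0.5 of its spots. This left 43838 of 60691 distinct probes (72.2%). No spot was saturated in any signal, a count of 0. Spots of a probe were averaged on the log2 scale. Each channel was divided by its median over usable probes, the m6A ratio was log2(IP/Sup), and abundance was log2(IP + Sup). A probe counted as higher or lower in cKO at a log2 difference of at least 1, a 2-fold size rule with no test, since there was 1 array per genotype. No p-value was computed.

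The files do not pair most probe IDs with genes. An accession stood beside 50 probes, each spotted 10 times, and 45 of these matched a symbol through a RefSeq gene table of mouse assembly GRCm38.p6. Of the 45 genes, 41 were usable. The other 60641 probes were used for counts and distributions without a name. Ptger3, Wtap, Zfp410, Chd4 and the m6A writers had no named probe, so their levels are not analysed here and expression gives no check of the genotype labels. The SD quoted for a gene is that between repeated spots of its probe, a technical spread.

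Before the data were examined, 38 gene lists and the rule for named genes were fixed. The rule took up to 12 genes per direction for the m6A difference and for abundance, and 8 per end for the control array's ratio. They had to have a symbol and be brighter than the median usable probe, which 29 genes were. Of these, 1 is included in the counts and is not shown singly. Lists needed 5 measured genes to be placed among random lists, and 0 lists reached that. Usable members were Gpi1 of the glycolysis list, Olfr166 and Olfr1307 of the olfactory receptor list, and Mbp of the Schwann cell and neuron list. The planned averaging over several probes of a gene had nothing to act on, since each named gene had 1 probe.

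The calculation was also tested on simulated data, with the noise taken from the repeated spots of these arrays. In 43838 simulated probes with spot noise as measured, 200 had a changed m6A ratio. The 2-fold rule took 95.5% of those changed 2.5-fold, 100% of those changed 4-fold and 1.49% of those changed 1.5-fold, and 0 unchanged probes. This simulation holds spot noise and no variation between animals or pools. Every probe had the same noise, an SD of 0.17 (log2) for the difference, so 0 unchanged probes past 2-fold followed from that setting. The dimmer named probes had a spot SD of 0.26. The shares therefore do not give the error rate of the rule on the real arrays. Alternatives covered background correction, scaling, filters, spike-in spots, the measure and the size threshold. Normexp with an offset of 50, loess and Aquantile were run in limma 3.58.1 under R 4.3.3, on pixel medians, since mean signals are not used here. Normexp alone thus carried no dye normalisation, unlike the processed signals. The offset shrinks the log ratios of dim probes toward 0, with or without loess. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.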

Results

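The m6A content of RNA was profiled in sorted mouse brown preadipocytes with and without the prostaglandin E2 receptor EP3. The series has 4 samples, the IP and Sup fractions of 1 control pool and of 1 EP3 cKO pool. Among 61054 array spots free of outlier flags, 79.1% were well above background in control IP, 76.3% in cKO IP, 80.8% in control Sup and 82.3% in cKO Sup. The median processed signal of usable probes was 474 in control IP, 413 in cKO IP, 468 in control Sup and 411 in cKO Sup. With 1 array per genotype, no difference below has a replicate check, and the number of arrays limits the precision. The pooled SD of repeated spots was 0.17 (log2) for the m6A difference and 0.10 for the abundance difference over 45 probes with 387 usable spots.

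The first comparison asked which transcripts had a high or low m6A ratio within the control preadipocytes. Lists of ribosomal protein genes and known m6A-rich transcripts were planned as checks of the low and high ends. Each had 0 usable members, so it was not checked here that the ratio follows m6A content. Taf1a, a subunit of the RNA polymerase I initiation factor, had a log2(IP/Sup) of 2.08 ± 0.12 (SD, n = 9 spots), among the highest of the named genes. Rab5a, a small GTPase of early endosomes, stood at 2.04 ± 0.08 (SD, n = 9 spots) and Uhrf1bp1l at 1.99 ± 0.11 (SD, n = 10 spots). The nuclear pore protein gene Nup50 stood at 1.87, Dnajc11 at 1.79 and Cpt1a, which encodes the carnitine palmitoyltransferase that controls entry of fatty acids into mitochondria, at 1.47. Carhsp1 at 1.13 and Bambi at 1.11 completed the upper 8. At the low end, Prdx2, a peroxiredoxin gene, stood at -1.52 ± 0.07 (SD, n = 8 spots) and Pex11a, a gene of peroxisome division, at -1.20 ± 0.11 (SD, n = 10 spots). The transcription factor gene Lhx1 stood at -0.71, the glutathione transferase gene Gsta4 at -0.64, Actb at -0.59, Anxa8 at -0.57 and Olfr166 at -0.48. Dye and fraction are the same thing within an array, so a probe's ratio also carries its own dye bias.

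The cKO array ranked transcripts in much the same order. Over 43838 probes, log2(IP/Sup) on the arrays correlated with a Pearson r of 0.895 and a Spearman rho of 0.875, across probes, which are not independent replicates. The 41 named usable genes gave an r of 0.869. IP exceeded Sup at least 2-fold for 7723 probes in control and 7136 in cKO, and lay at least 2-fold below it for 7476 and 6260. The SD of the ratio was 1.13 in control and 1.03 in cKO. After median scaling, the plot of the difference by level of the ratio goes from higher cKO ratios at the low end to lower ones at the high end. Another scaling constant would move all levels alike, so the plot does not show which end changed.

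**Figure D1:**
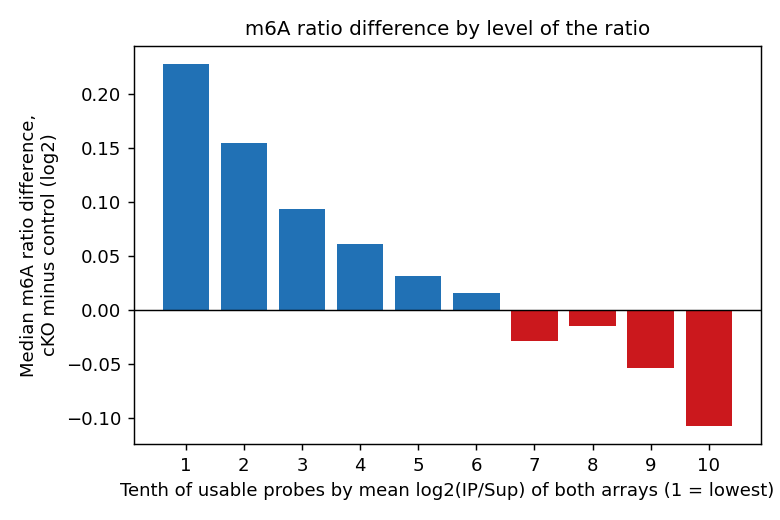
Median difference in log2(IP/Sup), cKO minus control (y axis, log2), for the usable probes sorted into 10 groups by their mean ratio on both arrays (x axis, 1 = lowest). Bars go from 0.23 in the lowest group to -0.11 in the highest. Each channel was scaled to its median, and another constant would move all bars alike.

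The main comparison asked how loss of EP3 went with the m6A ratio. Cav2, which encodes the caveolar membrane protein caveolin-2, had an m6A difference of -1.45 ± 0.13 (SD, n = 9 spots), from -0.03 in control to -1.49 in cKO. Lhfp stood at -1.12 ± 0.08 (SD, n = 10 spots), with 0.63 in control and -0.49 in cKO. With normexp the order was the other way, -1.22 for Cav2 and -1.29 for Lhfp. Bambi, a decoy receptor that dampens TGF-beta signalling, stood at -0.81 ± 0.06 (SD, n = 9 spots), and Gsta4 at -0.70 ± 0.09 (SD, n = 9 spots). On the other side, Rps4l, a ribosomal protein S4-like gene, had the highest difference, 0.74 ± 0.08 (SD, n = 9 spots), and Pex11a stood at 0.57 ± 0.10 (SD, n = 10 spots). Normexp gave 0.32 for Rps4l and 0.26 for Pex11a.

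Below these, a group of genes with control ratios above 0 lay between -0.55 and -0.30. It held the major histocompatibility class I genes H2-Q7 (-0.55) and H2-M2 (-0.52), Carhsp1 (-0.52), Nup50 (-0.51), Tm9sf1 (-0.50) and Gsdmd (-0.40), which encodes the pore-forming protein of pyroptosis. Acaa2, a thiolase gene of mitochondrial fatty acid oxidation, stood at -0.32, and Alkbh4 at -0.30. With normexp, which had no dye normalisation, this group lay between -0.95 for H2-Q7 and -0.43 for Alkbh4. With loess and Aquantile it lay between -0.46 for Carhsp1 and -0.23 for Acaa2. Higher ratios in cKO were measured for Anxa8 (0.43), Actb (0.42), Apoe (0.30), the creatine synthesis gene Gamt (0.30), Olfr166 (0.25), Prdx2 (0.24), Lhx1 (0.16) and Uhrf1bp1l (0.03). In all, 18 of the 29 bright named genes lay below 0 and 11 above, and in 17 and 8 of these every usable spot lay on that side. Among the 12 dimmer named genes, Trp53rka at -1.25 ± 0.32 (SD, n = 10 spots) and E2f1, a cell cycle transcription factor gene, at -1.05 ± 0.20 (SD, n = 10 spots) also reached 2-fold; they fall outside the naming rule and were chosen after their values were seen. Neither reached it with normexp, where Trp53rka stood at -0.46 and E2f1 at -0.41, or with loess and Aquantile, at -0.61 and -0.53.

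**Figure D2:**
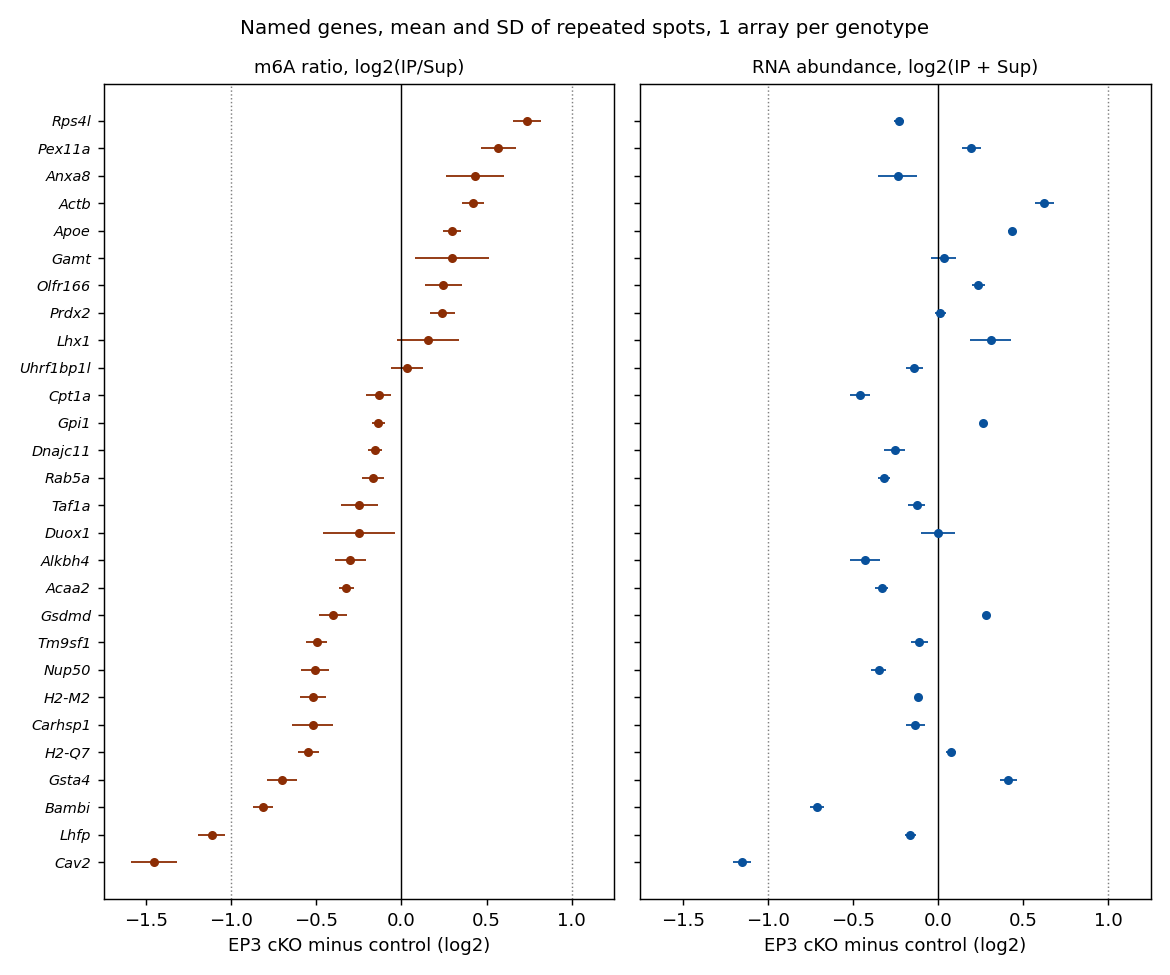
Differences between EP3 cKO and control (x axes, log2) in the m6A ratio (left) and in RNA abundance (right) for bright named genes; points are means over repeated spots of 1 array per genotype, bars their SD, dotted lines the 2-fold rule. Cav2 lies past 2-fold in both panels, at -1.45 and -1.15, and every m6A sign other than those of Cav2, Lhfp, Bambi, Gsta4, Rps4l and Pex11a turns under at least 1 other setting.

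Across all usable probes, 872 had an m6A ratio at least 2-fold higher in cKO and 1443 at least 2-fold lower, 5.28% in sum, so that 37.7% of these were higher. In the brighter part of the probes, 390 were higher and 759 lower. No single spot of the 387 repeated ones, a count of 0, lay a log2 of 1 or more from its probe's mean. Repeated spots share the same array per genotype, so this count holds no error between arrays. Of their 45 probes, 30 were brighter than the median probe. The median difference was 0.04, and 77.3% of probes lay within 1.5-fold. The probe ASMM10EP3A104025471 had one of the lowest differences, -2.55, and ASMM10EP3A113972547 and ASMM10EP3B102951520 were among the highest, at 3.91 and 2.96. For ASMM10EP3A113972547 both signals were far lower in cKO, with log2 differences of -6.29 in IP and -10.20 in Sup.

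The direction of the whole distribution was set by the scaling. In the authors' deposited table the median difference was -0.45. Over the usable probes its values moved the median by -0.48 and gave 113 higher and 5834 lower, 1.90% higher. Scaling to the spots named SPINKEIN moved the median by -0.21 and left 11.1% higher, and the channel medians of 5 ERCC spike-in probes moved it by 0.64, with 98.8% higher. That move runs opposite to the one called for by the ERCC probes' own median m6A difference of 0.35, and the means of the same 5 probes moved the median by -0.04, with 30.2% higher. Under the ERCC channel medians Cav2 stood at -0.82 and Lhfp at -0.48, short of 2-fold. Normexp on pixel medians, which also leaves out the scanner's dye normalisation, gave 13.7% higher. Normexp with loess and Aquantile gave 49.6%. The share under normexp alone can therefore not be credited to the background correction. Among 11 scalings, corrections and filters, the sign of the difference held in each that measured the gene for Cav2, Lhfp, Bambi, Gsta4, Rps4l and Pex11a. Cav2 was not among the 27 genes left by the filter for brightness in every signal. Only normexp, alone or with loess and Aquantile, recomputed the values of each probe. The other settings shift all probes by 1 constant per channel or change which spots and probes are used. They therefore test the sign against little more than such a shift, and the authors' table centred on the median gave the main counts again. H2-Q7, H2-M2, Carhsp1, Nup50, Tm9sf1, Gsdmd, Acaa2 and Alkbh4 turned above 0 under the channel medians of the ERCC spots and under none of the others that measured them, the ERCC means included. Under the authors' constants, Anxa8, Actb, Apoe, Gamt, Olfr166, Prdx2, Lhx1 and Uhrf1bp1l turned below 0. Normexp also turned Apoe (-0.02), Prdx2 (-0.15) and Uhrf1bp1l (-0.37), the SPINKEIN spots Lhx1 and Uhrf1bp1l, and the ERCC means Uhrf1bp1l.

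The next comparison asked how loss of EP3 went with RNA abundance, taken as the sum of both fractions. The fractions were labelled separately and each was scaled to its own median, so the sum only approximates the total RNA of a gene. Cav2 RNA was 2.22-fold lower in cKO, a log2 difference of -1.15 ± 0.05 (SD, n = 9 spots), made up of -2.06 in IP and -0.61 in Sup; with the ERCC channel medians its abundance difference was -0.94. Bambi stood at -0.71 ± 0.04 (SD, n = 9 spots), made up of -1.02 in IP and -0.21 in Sup. Cpt1a stood at -0.46 ± 0.06 (SD, n = 9 spots). Acaa2, which like Cpt1a serves fatty acid oxidation, stood at -0.33 ± 0.04 (SD, n = 6 spots). Actb was highest at 0.63 ± 0.06 (SD, n = 10 spots), with the lipoprotein gene Apoe at 0.44 ± 0.02 (SD, n = 6 spots) and Gsta4 at 0.41 ± 0.05 (SD, n = 9 spots).

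Lower values were also measured for Alkbh4 (-0.43), Nup50 (-0.35), Rab5a (-0.32), Dnajc11 (-0.25), Anxa8 (-0.24), Rps4l (-0.23), Lhfp (-0.16) and Uhrf1bp1l (-0.14). Higher values were measured for Lhx1 (0.31), Gsdmd (0.28), the glycolytic enzyme gene Gpi1 (0.27), Olfr166 (0.24), Pex11a (0.20), H2-Q7 (0.08), Gamt (0.03) and Prdx2 (0.01). Of the bright named genes, 16 lay below 0 and 13 above. Cav2, Bambi, Cpt1a, Acaa2, Alkbh4, Anxa8 and Rps4l stayed below 0, and Actb, Apoe, Gsta4, Lhx1, Gpi1 and Olfr166 above it, under every scaling, correction and filter that measured them. The sizes held less well with loess and Aquantile, where Gpi1 stood at 0.01 and Apoe at 0.17. The other genes listed turned sign under at least 1 setting. Mbp, the 1 measured marker of Schwann cells, had an abundance difference of 0.10 ± 0.15 (SD, n = 8 spots), with a sign that turned under 5 settings.

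Gsta4, Gsdmd and H2-Q7 combined a lower m6A ratio with a higher Sup signal, where they differed by 0.65, 0.51 and 0.42. Lhfp differed by -0.71 in IP and 0.41 in Sup. In Cav2 and Bambi the lower ratio came with a lower IP signal, -2.06 and -1.02. Gabrg1, a GABA receptor subunit gene, was not well above background in control in any of its 10 spots, in IP or Sup. In cKO it was so in 10 of 10 spots in IP and in 5 of 10 in Sup. Its cKO IP signal was at least 1.52-fold higher, from loess and Aquantile values that are open to dye bias without a dye swap.

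Over all probes, 758 were at least 2-fold higher in abundance in cKO and 819 at least 2-fold lower, so that 48.1% of these were higher. The share was 26.0% with no median scaling, 18.6% with the authors' constants, 32.7% with the SPINKEIN spots, 85.1% with the channel medians of the ERCC spots and 19.7% with their means. These moved the median abundance difference of all probes by -0.19 with no scaling, -0.22 with the authors' constants, 0.21 with the ERCC medians and -0.23 with the ERCC means. The probe ASMM10EP3A113972547, among the highest in the m6A difference, had the lowest abundance difference, -9.31, with -6.29 in IP and -10.20 in Sup. ASMM10EP3A110869525 stood at -4.31 and ASMM10EP3A100171738 at 4.84. Sup differed less between genotypes than IP. The SD over probes was 0.36 for the Sup difference and 0.58 for the IP difference, and 439 probes were at least 2-fold higher and 273 lower in Sup, against 1478 and 1979 in IP.

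The relation between the m6A difference and the abundance difference gave a Pearson r of 0.503 and a Spearman rho of 0.494 across probes, which are not independent replicates. Both measures share the same 4 signals. Against the Sup difference alone r was -0.112, and against the IP difference alone 0.795. Cav2 and Bambi were lower in both measures, while Gsta4 was lower in m6A and higher in abundance. A lower IP signal alone lowers both measures, and the Sup difference was -0.61 for Cav2 and -0.21 for Bambi. Of the 1443 probes with a lower m6A ratio, 292 were also at least 2-fold lower in abundance and 651 lay within 1.5-fold; of the 872 with a higher ratio, 233 were also higher in abundance and 487 lay within 1.5-fold.

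Control spots named for mouse Gapdh and Pgk1 come in sets named 3 and 5, whose gap also carries the affinity of different probes. Gapdh spots named 3 exceeded those named 5 by 1.88 (log2) in control IP, 1.79 in cKO IP, 2.25 in control Sup and 1.89 in cKO Sup. For Pgk1 the gap was 7.80 in control IP, 8.68 in cKO IP, 7.45 in control Sup and 7.81 in cKO Sup. Gapdh spots had m6A differences of 0.35 and 0.08, and Pgk1 spots of -0.76 and -1.28, for the spots named 3 and 5. The authors' constants, which move the median of all probes by -0.48, place both Gapdh values below 0, and the SPINKEIN shift of -0.21 places the lower one there. Abundance differences were 0.27 and 0.55 for Gapdh and -0.03 and -0.48 for Pgk1, for the spots named 3 and 5. Spot SDs in either measure were at most 0.20, so the sets for a gene lay further apart than their spots scattered. The SD quoted for a named gene, from 1 probe, does not cover such a gap.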

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

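Among the tests in this part, those of dye normalisation, of carry-over and of noise of one channel were chosen after the result was seen. The spots named as spike-ins, used here for alternative scalings alone, had median IP differences above 0 after scaling to the array probes. The median, cKO minus control, was 0.42 (log2) over 5 ERCC probes, 3 of them higher and 2 lower, and 0.20 over 57 SPINKEIN probes, 40 higher and 17 lower. In the m6A ratio the medians were 0.35 for ERCC and 0.17 for SPINKEIN, with SDs over probes of 0.46 and 0.36, while 15 probes named CUST had a median of -0.19. The labels do not say whether any of these RNAs was added, or in what amount.

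The range of m6A ratios was narrower on the cKO array, with an SD 0.916 times that of control. Dye normalisation by the scanner software is argued against, because the quotient was 0.917 in pixel medians minus local background, which carry none. Carry-over of unbound RNA into the cKO IP would raise the ratios of the poorest transcripts most; with a carried share of 0.063 set on the lowest of 10 groups of probes, modelled and observed medians differed by up to 0.0807 in the other 9, with the largest difference at the top, and since the profile is assumed this leaves carry-over open. A lower m6A content of the richest transcripts in the cKO cells, the biological explanation the design offers, may also narrow the range at the top and was not tested. With each channel scaled to its median, the median difference was -0.11 in the highest group of probes and 0.23 in the lowest. A scaling constant moves all groups alike, and the authors' constants moved the median of all probes by -0.48. Which end differed more therefore depends on the scaling and does not bear on this explanation. With 1 array per genotype, carry-over and genotype cannot be told apart.

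Abundance differed at least 8-fold for 28 probes, 22 of them lower and 6 higher in cKO. Noise of one channel is argued against, because 100% of them differed at least 4-fold the same way in IP and Sup. Selection by the summed signal left room for a brightened channel, since brightening IP alone 32-fold would carry 95.1% of usable probes past 8-fold; a dimmed channel would mostly not be selected. A defect that clustered most of these probes on an array is argued against too: the median distance to the nearest other probe of the set was 23.8 spots, at the 51.9th percentile of 1000 random sets. Being a median over the set, this distance could miss a cluster of a minority of the probes. Neither result bears on such a cluster or on a defect confined to single spots, which were not tested and stay open. These probes have no gene names here, so RNA of another cell type in 1 pool, and an effect of the genotype, were not tested and stay open.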

How the results depend on the processing

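No paired analysis was possible because each genotype has 1 sample, and no replicate could be left out. Chosen after seeing the data were the authors' table as deposited, the SPINKEIN spots, the mean of the ERCC spots and the axes from different spots. Leaving out saturated probes removed 0 probes. Not run, for want of named probes, were the alternatives on several probes of a gene, axes from different probes, and all gene list medians. The authors' table centred on the median and 75th percentile scaling kept every count within 1.5 times. Of the values of the 41 named genes across settings (27 genes under the filter for brightness), 279 m6A and 197 abundance values moved by less than the SD of spots, and 158 m6A and 240 abundance values by more. None of those at least 2-fold turned sign, a count of 0 among these settings. Signal over background limits the dim probes, whose spot SD for the m6A difference was 0.26 against 0.11 in bright ones.

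Counts are given as higher then lower in cKO, first for m6A (main 872 and 1443), then for abundance (main 758 and 819). Normexp gave 165 for m6A higher, and 383 and 411 for abundance. Normexp with loess and Aquantile gave 495 and 502, then 367 and 404. Without the background filter there were 2685 and 3840, then 1420 and 1539, over 60669 probes. Probes brighter than the median in every signal, 17844 by construction, gave 270 and 558, then 333 and 236. The channel medians of the ERCC spots gave 10481 and 126, then 1311 and 230. The mean of the same 5 probes gave a median m6A difference of 0.00031, with 721 and 1667 for m6A and 2117 lower in abundance, so the ERCC direction depended on how 5 unequal probes were summarised: their own m6A differences ran from -0.64 to 0.39. The authors' constants gave 113 and 5834, then 407 and 1787. The SPINKEIN spots gave 341 and 2739, then 1422 lower in abundance. With no median scaling 1477 were lower in abundance. IP alone gave 1478 higher as a measure of m6A, and 1478 and 1979 as one of abundance. Sup alone gave 439 and 273 in abundance, and the mean of logs 485 lower. At 1.5-fold, by construction, there were 4976 and 4964, then 2461 and 2970. Ranking by the share IP/(IP+Sup) kept 661 of 872 higher and 1191 of 1443 lower probes.

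Within arrays, counts are of IP at least 2-fold above then below Sup (main 7723 and 7476 in control, 7136 and 6260 in cKO). Normexp gave 3851 below in control, and 4022 and 3903 in cKO. Loess and Aquantile gave 3712 below in control and 2880 in cKO. Without the filter 9819 lay below in cKO. The brightest probes gave 3403 and 3769 in control, 3141 and 3231 in cKO. The ERCC medians gave 3741 and 15914 in control, and their means 16009 and 2256 in control and 14998 and 1770 in cKO. The authors' constants gave 4873 and 12482 in control, 2094 and 20752 in cKO. The SPINKEIN spots gave 17561 and 1901 in control, 13952 and 2015 in cKO. The r between arrays was 0.831 without the filter.

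The r of the m6A against the abundance difference (main 0.503) was 0.564 with loess and Aquantile, 0.344 without the filter, 0.431 with the ERCC medians, 0.590 with their means, 0.426 with the authors' constants and 0.594 with SPINKEIN. It was -0.112 with Sup alone, a turn of sign, and 0.795 with IP alone. Axes from different spots of 45 probes gave 0.588, against 0.609 from the same spots. Where the construction of a setting does not show it, the cause was not tested.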

Other observations

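Probe IDs fall into series whose meaning is not given in the sources used here. The 2754 usable probes of the SM series had a median log2(IP/Sup) of -0.40 in control and -0.30 in cKO, against -0.04 and -0.05 for 35680 probes of the EP3A series. Their median m6A difference was 0.20, against 0.03 for EP3A and 0.06 for EP3B. At least 2-fold higher ratios in cKO were found for 78 SM probes and lower ones for 47, while EP3A had 670 and 1246. In abundance, 65 SM probes were higher and 16 lower, and in EP3A 587 and 741. The authors' constants move the median of all probes by -0.48 and the SPINKEIN spots by -0.21, and either shift places the SM median below 0.

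Some genes best known from other tissues gave signals brighter than the median usable probe. Among them were Olfr166, an olfactory receptor gene, and the transcription factor gene Lhx1. Both had control ratios below 0.

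Detection was uneven between genotypes. In IP, 2648 spots were well above background in control and not in cKO, against 937 the other way. In Sup the order was the opposite, with 912 in control and 1852 in cKO.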
